A study of Mus musculus with 12 samples.

How the data were processed

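RNA sequencing of 12 bone marrow samples of C57BL/6 mice was used: 3 untreated samples taken 10 days after intravenous injection of Vk12653 myeloma cells, and 3 samples each at days 4, 11 and 18 of treatment with the CD137 agonist antibody 3H3. Per the labels, libraries were made with a stranded mRNA kit from 100 to 300 ng of RNA with an integrity number above 8, and sequenced as pairs of 150 bp reads to an average of 20 M pairs. The processing notes of the authors name STAR 2.3.0, Subread featureCounts 1.4.6, limma and the mouse genome build GRCm38, without saying in which step each served. The strand setting used for counting is not given in the labels used here. Per the file headers, the values of the 1 table used are normalised counts, a score deposited as whole numbers. The headers do not say how the counts were scaled. They were taken here to be read counts per gene, divided by 1 factor per sample and then rounded. This is an assumption, and the estimates of depth below rest on it. The factors themselves are not in the table. They were estimated here from the whole numbers that are missing or doubled among low values, using values up to 150 and a grid step of 0.0005, and ranged from 0.768 to 1.262. On simulated tables made by the same rule, with factors that lie on the grid, the method returned them with a largest error of 0.0%. This does not measure the error on the deposited values. The factors estimated from the deposited values give 16 to 25.2 M assigned reads per sample. They served to describe depth, for alternatives on depth and for tests of depth as an explanation.

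All 23134 gene identifiers, with their versions, were found in GENCODE mouse release M21, which gave positions; 248 symbols differ from that release and are printed as in the table. Duplicated symbols, 9 in number, were kept apart by identifier. No technical batch, pairing or collection date is given in the labels, and replicate numbers follow the order of the samples only. The 12 pairs of replicates within groups differed in counts by 9.9 to 42.99 chi-square units per gene over 10456 genes with a mean normalised count of at least 50. Of all 66 pairs of samples, within and across groups, 0 were identical, and a pair had equal values in at most 0.93% of those genes, so no sample was a copy of another.

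Values were transformed as log2 of the normalised count plus 1. Genes with at least 10 normalised counts in at least 3 samples were kept, which left 14883 genes and removed 8251. One linear model with a mean per group was fitted to all 12 samples in limma 3.58.1 under R 4.3.3, with an empirical Bayes intensity trend (8 residual and 5.73 prior degrees of freedom). Each treated day was compared with untreated marrow, treated days were compared with each other, and an F-test covered the 4 time points. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and calls were made at a threshold of 0.05. A comparison of treated days is also the test of whether their changes from untreated marrow differ. Means are given with the SD between the 3 samples of a group, and log2 changes with the SE of the model.

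Gene lists, 36 in number with 537 distinct genes, were written from textbook markers and pathways, and 439 of the genes are in the table. They cover T cells (core, cytotoxic effector, activation and checkpoint, regulatory), natural killer cells, CD137 and NF-kB costimulation, interferon gamma and type I interferon responses, MHC class I and class II presentation, inflammatory cytokines and chemokines, and the secretory and unfolded protein response. B lineage lists are plasma cell and myeloma, immunoglobulin constant region, B cell precursor and mature B cell. Other marrow lists are erythroid, mature neutrophil, neutrophil primary granule, monocyte, resident macrophage, conventional and plasmacytoid dendritic cell, eosinophil, basophil and mast cell, stem and progenitor, megakaryocyte, osteoblast, osteoclast, stroma, endothelial and adipocyte lists. The last lists are cell cycle, immediate early and heat shock, mitochondrial transcripts and skeletal muscle. In bulk RNA a list describes transcripts, not numbers of cells, and some genes stand in more than one list. Of the lists, 34 had at least 3 tested genes and were tested with fry of limma against untreated marrow, with adjustment over the 102 tests. The MHC class II list had too few tested genes and the mitochondrial list had none, so neither was tested as a set. Calls of members are given over all genes tested and adjusted over the list alone.

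Genes named in the text were taken by a rule: Tnfrsf9 and Tnfsf9, the largest rises and falls among called genes whose treated and untreated samples do not overlap (leaving out predicted genes, pseudogenes and variable segments of antigen receptors), the members with the smallest adjusted p of each list with at least 3 called members, and other list members where a list is described. The comparisons, the model, the filter, the lists, this rule and most alternatives were fixed before the data were examined.

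The method was tested on simulated data with the size of these groups and the spread of each gene pooled over them, in which 200 genes were changed. The changed genes were drawn only from those above a minimum mean, so recovery of the lowest genes kept by the filter was not measured. All samples had the same spread, so noisier single samples were not imitated. At day 4 against untreated marrow, 51% of genes changed by 1.5-fold, 79% of those changed by 2-fold and 95% of those changed by 4-fold were called. The values were 56.5%, 81.5% and 94% at day 11, and 56.5%, 79% and 98% at day 18. For fry, all 4 of 40 simulated lists of 16 genes that were shifted by 0.5 on the log2 scale were called, and 0 others. Group means had been made equal for every gene before the shift. That 0 others were called was therefore fixed in advance and does not measure false calls. The genes of these lists were drawn at random, so correlation within the lists tested was not imitated.

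Alternatives were pseudocounts of 0.1, 0.5 and 4, no filter, a mean normalised count of at least 40, quantile normalisation, median-of-ratios rescaling, rescaling by a trimmed mean of ratios with abundant, immunoglobulin and haemoglobin genes left out, no intensity trend, a robust trend, sample weights, only the 2 groups compared, a log2 change of at least 1, each sample left out in turn, and camera with a preset correlation of 0.01 or an estimated one. Added after seeing the data were random thinning of every library to the lowest estimated depth, voom precision weights, and the logarithm of the estimated depth as a covariate. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.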

Results

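Bone marrow RNA was profiled from C57BL/6 mice carrying Vk12653 cells, a transplantable line from the Vk*MYC mouse model of multiple myeloma that was given by intravenous injection. One group of 3 samples was untreated marrow taken 10 days after the injection, which is day 0 of treatment. The other 9 samples came from mice that received an agonist antibody to CD137, a costimulatory receptor of activated T cells, as intraperitoneal doses of 10 µg of clone 3H3. They were taken at treatment days 4, 11 and 18, which are days 14, 21 and 28 after the injection of myeloma cells, with 3 samples per day. The series asks what CD137 agonists do to the marrow environment of myeloma. Antibody exposure and days since myeloma injection rise together, and untreated marrow of the later days is not analysed here, so every change from day 0 holds both. The table gives normalised read counts for 23134 genes. The normalised total ranged from 19.16 M to 20.84 M per sample. The number of reads behind it, estimated from the spacing of low values, was 25.2, 23 and 21.6 M in the untreated samples. It was 16, 17.8 and 16.7 M at day 4, then 24.3, 16.8 and 20.0 M at day 11 and 23.6, 20.6 and 18.5 M at day 18. The day 4 libraries were therefore the shallowest as a group, and 2189 to 2548 genes stood at 0 in them, against 1505 to 1723 in untreated marrow. The later days also had more genes at 0 than untreated marrow, with 1927 to 2520 at day 11 and 1791 to 2255 at day 18. The most abundant transcripts were those of S100a9, S100a8, Ngp and Ltf, which neutrophils express and which held 7.3% of the total. On the main axis of variation, with 27.9% of the variance, untreated samples lay between -33.4 and -31.6, day 4 between -14.3 and -9.8, day 11 between 14.9 and 19.5, and day 18 between 20.4 and 32.4. P-values below measure only the spread between these samples, since the labels do not state how many mice stand behind each one.

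The first comparison asks what had changed in marrow after 4 days of antibody. Fos, a transcription factor subunit made within minutes to hours of stimulation, went from a mean of 2560 ± 993 normalised counts (SD, n = 3) before treatment to 20100 ± 3210 at day 4, a log2 change of 3.02 ± 0.25 (SE, adjusted p = 6.76e-06). Its partner Jun rose from 1290 ± 491 to 15800 ± 1300 (log2 change 3.67 ± 0.25, adjusted p = 9.39e-07). Tnfrsf9, which encodes CD137 itself, went from 36 ± 7.81 to 224 ± 65.4 (log2 change 2.58 ± 0.28, adjusted p = 9.51e-05), and the granzyme gene Gzmk from 6 ± 2.65 to 171 ± 53.9 (log2 change 4.63 ± 0.26, adjusted p = 2.46e-07). Tnfrsf9 is identified as ENSMUSG00000028965.13 and lies on the plus strand of chromosome 4 from 150914562 to 150946102 in GRCm38. Tnfsf9, which encodes its ligand, is not analysed here.

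Of 14883 genes tested at day 4 with limma, 357 rose and 334 fell. Which direction was the more frequent changed with the setting: 305 rose and 397 fell after quantile normalisation, 338 and 356 after rescaling by a trimmed mean, 280 and 283 with no filter, and 266 and 270 with only the 2 groups compared. Without day 4 replicate 1 it was 271 and 295, and without day 18 replicate 3 543 and 546, while 142 rose and 47 fell by a log2 change of at least 1. Of the 691 genes called, 689 had no overlap between the treated and the untreated samples. Across all genes tested, 25.5% had no overlap, where chance gives 10%. The count was 313, 381 and 295 without untreated replicate 1, 2 or 3, it was 400 and 269 without day 4 replicate 2 or 3, and 1089 without day 18 replicate 3. It was 416 with no intensity trend, 1817 with sample weights, and 69, with 59 higher and 10 lower, with the estimated depth as a covariate, which parts the day 4 from the untreated libraries.

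The list of immediate early and heat shock genes, which also serves as a sign of how tissue was handled, had 8 of 9 tested members higher at day 4 and none lower. Adjusted over the list alone, 9 were higher. Besides Fos and Jun, Fosb rose from 169 ± 132 to 7500 ± 1660 and the stress-response gene Atf3 from 113 ± 24.8 to 1450 ± 396. The set test, fry, gave an adjusted p = 3.98e-05, and camera with an estimated correlation gave an adjusted p = 0.0603. The rotation test fry asks whether a list's genes move on balance one way, and its mixed form whether they change in either direction. Neither compares a list with other genes, as the test named camera does. Every value given with an estimated correlation, here and below, comes from camera and so answers a different question from fry. Outside that list, Rgs1, a regulator of chemokine receptor signalling, was among the largest rises and went from 65 ± 25.2 to 1950 ± 159, a log2 change of 4.97 ± 0.23 (adjusted p = 8.69e-08). The neutrophil chemokine Cxcl2 rose from 109 ± 56.6 to 2730 ± 1290 and Lad1, an anchoring filament gene, from 2.67 ± 1.53 to 74.7 ± 23.1. Inflammatory cytokines and chemokines had 5 of 16 members higher and none lower, and 6 higher and 1 lower adjusted over the list alone, with Ccl2 at 12.7 ± 8.14 before and 115 ± 21.7 at day 4 (set test adjusted p = 0.00702, and adjusted p = 0.221 with an estimated correlation). The CD137 and NF-kB list had 5 of 13 members higher and none lower, and 6 higher and 1 lower adjusted over the list alone. Its set test gave an adjusted p = 0.00277, and adjusted p = 0.177 with an estimated correlation. In it, Tnfaip3, a feedback inhibitor of NF-kB, rose from 830 ± 91.7 to 2840 ± 433. Tnfaip3, Ccl2, Cxcl2 and Rgs1 were lower again at day 11, as immediate early genes were. For these genes too, an effect of handling cannot be told apart.

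Cytotoxic effector transcripts had 7 of 17 members higher at day 4 and 1 lower, and 11 higher and 1 lower adjusted over the list alone (set test adjusted p = 0.00112, and adjusted p = 0.15 with an estimated correlation). Ccl4, a chemokine released by activated lymphocytes, rose from 69 ± 27.1 to 630 ± 89.4, and Klrg1, a receptor of effector T cells, from 16.7 ± 3.51 to 97 ± 34.4. The checkpoint list had 4 of 14 members higher and none lower, and 7 higher adjusted over the list alone, led by the inhibitory receptor Pdcd1 at 18 ± 3.61 before and 118 ± 44.4 at day 4 (set test adjusted p = 0.00399, and adjusted p = 0.168 with an estimated correlation). T cell core transcripts had 3 of 16 members higher, and 14 adjusted over the list alone, with a median log2 change of 0.75. Their set test gave an adjusted p = 0.0549 with fry, while camera at a preset correlation gave an adjusted p = 2.3e-07, and adjusted p = 0.326 with an estimated correlation. The called members Trac, Cd247 and Zap70 lost their calls with the depth covariate. Their log2 changes were then 0.6 ± 0.31, 0.57 ± 0.39 and 0.77 ± 0.27. In that list Cd8a stood at 367 ± 124 before and 630 ± 254 at day 4 (adjusted p = 0.128), and Cd4 at 711 ± 116 and 654 ± 24 (adjusted p = 0.744). The regulatory T cell list had 1 of 6 members higher, and 3 adjusted over the list alone (set test adjusted p = 0.00804, and adjusted p = 0.15 with an estimated correlation), and Foxp3 is not analysed here.

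Interferon gamma response genes had 6 of 27 members higher at day 4 and 1 lower, and 13 higher and 1 lower adjusted over the list alone, with a set test adjusted p = 0.0788 by fry, while camera at a preset correlation gave an adjusted p = 2.08e-05, and adjusted p = 0.36 with an estimated correlation. Genes of MHC class I presentation had 5 of 12 members higher, and 10 adjusted over the list alone (set test adjusted p = 0.00199, and adjusted p = 0.135 with an estimated correlation). The class I gene H2-Q6 went from 3150 ± 279 to 4900 ± 343 (log2 change 0.64 ± 0.09, adjusted p = 0.000903). With the depth covariate its log2 change was 0.42 ± 0.11 (adjusted p = 0.179), a smaller change with a wider SE. Every other called member of the interferon gamma and MHC class I lists also lost its call with the covariate. Secretory and unfolded protein response genes had 4 of 14 members higher, and 8 adjusted over the list alone, with the chaperone gene Dnajb9 at 636 ± 58.5 before and 1450 ± 81.3 at day 4 (set test adjusted p = 0.000101, and adjusted p = 0.0603 with an estimated correlation). Cell cycle genes had 6 of 22 members higher, and 18 adjusted over the list alone, by small amounts: the median log2 change was 0.25 (set test adjusted p = 0.00358, and adjusted p = 0.177 with an estimated correlation). The 6 called members, Tyms, Mcm3, Mcm4, Mcm5, Pcna and Rrm2, lost their calls with the depth covariate, under wider SEs. Neutrophil primary granule genes had 3 of 12 members higher, and 9 adjusted over the list alone (set test adjusted p = 0.0398, and adjusted p = 0.326 with an estimated correlation). That adjusted p was 0.069 after quantile normalisation, and 0.05 to 0.114 without untreated replicate 1, 2 or 3, day 4 replicate 1 or 3, day 11 replicate 3, or day 18 replicate 2 or 3. The 3 members called were Cst7, Nkg7 and Mpo. They too lost their calls with the depth covariate, and set tests were not repeated with it for any list. Nkg7 stands in the cytotoxic effector list too, so a rise of this list need not mark neutrophils alone.

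Mature B cell transcripts went the other way. Of 12 members 5 were lower and none higher, and 10 were lower adjusted over the list alone (set test adjusted p = 0.0398, and adjusted p = 0.313 with an estimated correlation). Fcer2a, the low-affinity IgE receptor of mature B cells, fell from 879 ± 253 to 309 ± 32.8 (log2 change -1.47 ± 0.24, adjusted p = 0.0032). With the depth covariate its log2 change was -1.39 ± 0.37 (adjusted p = 0.176), so the call ended with the wider SE while the change was about as large. Bank1, Ighd, Cd22 and Ralgps2, the other called members, lost their calls too. The list's adjusted p was 0.0518 to 0.132 without untreated replicate 2 or 3, day 4 replicate 1 or 3, day 11 replicate 1, 2 or 3, or day 18 replicate 3.

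**Figure D1:**
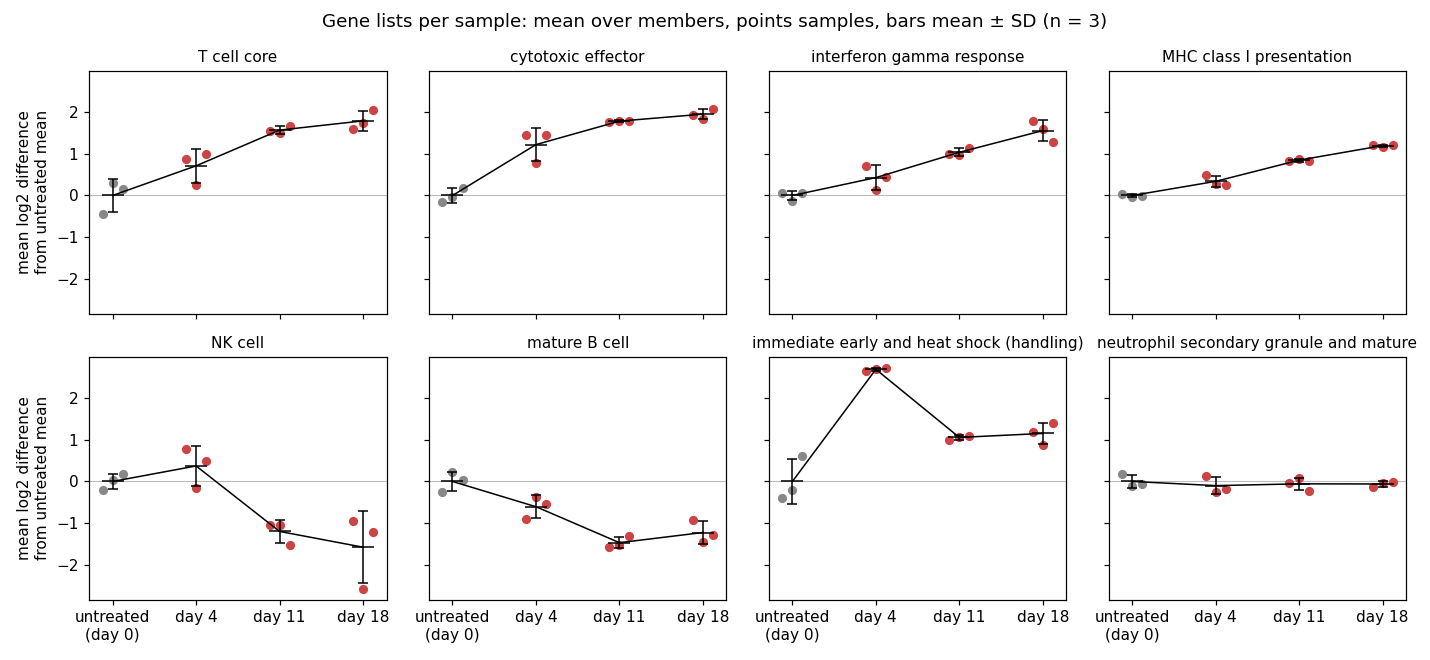
Mean log2 difference from the untreated mean over the members of chosen gene lists, in untreated marrow and at treatment days 4, 11 and 18. Points are samples and bars are mean ± SD, with 3 samples per group. The lists are T cell core, cytotoxic effector, interferon gamma response, MHC class I, natural killer, mature B cell, immediate early and heat shock, and mature neutrophil. T cell, interferon gamma and MHC class I lists lie higher at day 18 than at day 4. Medians of log2 changes over members, which are not drawn, were 0.75 at day 4 and 1.93 at day 18 for T cell core. For the natural killer list they were 0.29 at day 4 and -1.78 at day 18.

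The second comparison asks the same of day 11. Gzmk rose from 6 ± 2.65 to 761 ± 117, a log2 change of 6.82 ± 0.26 (adjusted p = 6.92e-09), and Pdcd1 from 18 ± 3.61 to 367 ± 91.2 (log2 change 4.26 ± 0.26, adjusted p = 6.46e-07). Cd8a, a chain of the CD8 coreceptor, rose from 367 ± 124 to 1610 ± 51.1 (log2 change 2.19 ± 0.27, adjusted p = 0.000245), whereas Cd4 stood at 711 ± 116 and 836 ± 169 (adjusted p = 0.45). Tnfrsf9 was higher than before treatment, at 243 ± 101 (log2 change 2.65 ± 0.28, adjusted p = 5.91e-05). Fcer2a was lower, at 121 ± 28.5 against 879 ± 253 (log2 change -2.83 ± 0.24, adjusted p = 1.09e-05).

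At day 11 476 genes rose and 316 fell, 792 in all, and 786 of them had no overlap between the treated and the untreated samples. Over all genes tested 26.4% had none, where chance gives 10%. The count was 502, 450 and 442 without untreated replicate 1, 2 or 3, and 407 and 449 without day 11 replicate 1 or 3. It was 521 with no intensity trend, 1914 with sample weights and 442 with the estimated depth as a covariate.

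Of the 16 T cell core members, 15 rose and 1, Cd4, did not pass, and the same numbers held adjusted over the list alone (set test adjusted p = 0.00162, and adjusted p = 0.135 with an estimated correlation). The receptor chain gene Trac rose from 186 ± 47.4 to 780 ± 93.9, and the signalling kinase gene Zap70 from 172 ± 25.5 to 572 ± 64.4. Cytotoxic effector genes had 11 of 17 members higher and none lower, and 12 higher adjusted over the list alone (set test adjusted p = 0.000133, and adjusted p = 0.135 with an estimated correlation). Gzmb rose from 90 ± 13.7 to 691 ± 190 and Ifng, which encodes interferon gamma, from 7.33 ± 3.21 to 50.7 ± 1.53. Of the 14 checkpoint genes 9 rose, and 10 adjusted over the list alone (set test adjusted p = 0.000266, and adjusted p = 0.11 with an estimated correlation). Tox, a transcription factor of chronically stimulated T cells, went from 40.3 ± 9.29 to 384 ± 130 (log2 change 3.19 ± 0.27, adjusted p = 1.09e-05). Regulatory T cell genes had 2 of 6 members higher and 1 lower, and 3 higher and 1 lower adjusted over the list alone. Their set test did not pass, with an adjusted p = 0.0551 by fry. Camera gave an adjusted p = 0.145 at a preset correlation and 0.313 with an estimated correlation. The member that fell was Il2ra (log2 change -0.81 ± 0.2, adjusted p = 0.0347 with limma). With the depth covariate Il2ra had -0.57 ± 0.19 (adjusted p = 0.145). The CD137 and NF-kB list had 5 of 13 members higher, and 5 higher and 1 lower adjusted over the list alone (set test adjusted p = 0.0421, and adjusted p = 0.36 with an estimated correlation). Its adjusted p was 0.0537 to 0.131 without untreated replicate 1, 2 or 3, day 4 replicate 1 or 3, day 11 replicate 1 or 3, or day 18 replicate 3. It was 0.0521 with a pseudocount of 0.1 and 0.0796 with a mean normalised count of at least 40.

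Interferon gamma response genes had 17 of 27 members higher and 1 lower, and 21 higher and 1 lower adjusted over the list alone (set test adjusted p = 0.00129, and adjusted p = 0.135 with an estimated correlation). The T cell chemokine gene Cxcl9 rose from 86 ± 24.3 to 529 ± 88.6 and the GTPase gene Gbp2 from 529 ± 90.8 to 2380 ± 198. The member that fell was Ciita, the master regulator of MHC class II genes, from 955 ± 198 to 455 ± 97.3 (log2 change -1.07 ± 0.21, adjusted p = 0.00909). With the depth covariate its log2 change was -0.88 ± 0.22 (adjusted p = 0.0508), a smaller change. Of the MHC class II list 2 genes were tested, Ciita and the protease gene Ctss, and no set test was run. MHC class I genes had 11 of 12 members higher, and 12 adjusted over the list alone, with H2-Q6 at 3150 ± 279 before and 9590 ± 911 at day 11 and the class I regulator Nlrc5 at 1600 ± 235 and 4100 ± 73 (set test adjusted p = 1.92e-05, and adjusted p = 0.0603 with an estimated correlation). The type I interferon list had 1 of 21 members higher, over all genes and adjusted over the list alone, and a set test adjusted p = 0.412 by fry, while camera at a preset correlation gave an adjusted p = 0.00786, and adjusted p = 0.65 with an estimated correlation. The difference between both interferon lists was not tested. Inflammatory cytokines and chemokines had 3 of 16 members higher, and 6 higher and 1 lower adjusted over the list alone, among them Ccl8 at 1.67 ± 1.53 before and 27 ± 6.56 at day 11 (set test adjusted p = 0.03, and adjusted p = 0.299 with an estimated correlation). Without untreated replicate 2, day 4 replicate 3, or day 11 replicate 1, 2 or 3, that adjusted p was 0.0584 to 0.0674.

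Of 12 mature B cell genes 11 fell, and all 12 adjusted over the list alone (set test adjusted p = 0.000568, and adjusted p = 0.135 with an estimated correlation). The B cell antigen gene Ms4a1 went from 2540 ± 315 to 715 ± 166, and Bank1, a B cell signalling scaffold, from 897 ± 144 to 312 ± 25.4. Immunoglobulin constant region genes had 6 of 12 members lower and none higher, and 10 lower adjusted over the list alone (set test adjusted p = 0.00399, and adjusted p = 0.135 with an estimated correlation), with the light chain gene Iglc2 at 311 ± 63.8 before and 112 ± 29.9 at day 11. B cell precursor genes had 5 of 12 members lower, and 6 adjusted over the list alone. Their set test gave an adjusted p = 0.104 with fry, while camera at a preset correlation gave an adjusted p = 0.000499, and adjusted p = 0.378 with an estimated correlation. The plasma cell and myeloma list had 2 of 14 members higher and 5 lower, and 2 higher and 8 lower adjusted over the list alone (set test adjusted p = 0.0646, mixed form 4.51e-06), while camera at a preset correlation gave an adjusted p = 0.0351, and adjusted p = 0.326 with an estimated correlation. Its falls included the plasma cell surface gene Sdc1, from 502 ± 151 to 266 ± 38.7. Its rises were Cd28 and Prdm1, which activated T cells also express, with Prdm1 at 86.3 ± 14.2 before and 210 ± 50 at day 11.

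Immediate early and heat shock genes were still above the untreated level at day 11, with 6 of 9 members higher, and 7 adjusted over the list alone (set test adjusted p = 0.00399, and adjusted p = 0.135 with an estimated correlation). Jun stood at 3610 ± 658 against 1290 ± 491 (adjusted p = 0.00236). Cell cycle genes had 6 of 22 members higher, and 18 adjusted over the list alone, with a median log2 change of 0.22 (set test adjusted p = 0.00399, and adjusted p = 0.184 with an estimated correlation). Secretory and unfolded protein response genes had 4 of 14 members higher, and 8 adjusted over the list alone (set test adjusted p = 0.00192, and adjusted p = 0.135 with an estimated correlation). Basophil and mast cell genes had 4 of 9 members higher, and 6 adjusted over the list alone (set test adjusted p = 0.0245, and adjusted p = 0.24 with an estimated correlation). That adjusted p was 0.0796 without untreated replicate 3 and 0.0575 and 0.0706 without day 11 replicate 1 or 3. Neutrophil primary granule genes had 3 of 12 members higher, and 7 adjusted over the list alone (set test adjusted p = 0.036, and adjusted p = 0.326 with an estimated correlation). That value was 0.0524 after quantile normalisation, and 0.05 to 0.111 without untreated replicate 1, 2 or 3, day 4 replicate 1, day 11 replicate 1 or 3, or day 18 replicate 2.

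Among single genes at day 11, the largest rises outside these lists began from very low values. Apol11a, an apolipoprotein L family gene, went from 6.33 ± 3.21 to 126 ± 66.1 (adjusted p = 3.37e-05), the membrane protease gene Tmprss13 from 3.33 ± 1.53 to 68 ± 15.4 (adjusted p = 5.98e-06), and Faxc from 2.33 ± 0.577 to 48.7 ± 11.6 (adjusted p = 0.00102). Gcg, which encodes proglucagon, had a mean of 0.333 ± 0.577 before treatment and 45 ± 34.6 at day 11 (adjusted p = 0.000313). Cacna1i, a calcium channel gene, fell from 375 ± 100 to 63 ± 12.3 (log2 change -2.53 ± 0.23, adjusted p = 2.21e-05).

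The third comparison sets day 18 against untreated marrow. Gzmk stood at 1000 ± 175 against 6 ± 2.65 (log2 change 7.22 ± 0.26, adjusted p = 3.23e-09) and Pdcd1 at 690 ± 106 against 18 ± 3.61 (log2 change 5.19 ± 0.26, adjusted p = 4.79e-08). Tgtp1, an interferon-induced GTPase, rose from 83 ± 6.56 to 762 ± 129 (log2 change 3.17 ± 0.18, adjusted p = 1.5e-07). Ncr1, an activating receptor of natural killer cells, fell from 234 ± 36.4 to 65.3 ± 46.5 (log2 change -2.12 ± 0.45, adjusted p = 0.00917). Tnfrsf9 stood at 354 ± 12.5 against 36 ± 7.81 (log2 change 3.28 ± 0.28, adjusted p = 3.86e-06).

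At day 18 787 genes rose and 582 fell, 1369 in all, of which 1349 had no overlap between the treated and the untreated samples. Over all genes tested 26.3% had none, where chance gives 10%. The count was 863 and 810 without untreated replicate 2 or 3, 804 without day 18 replicate 2, and 2056 with sample weights.

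T cell core genes had 15 of 16 members higher, and 16 adjusted over the list alone (set test adjusted p = 0.000844, and adjusted p = 0.135 with an estimated correlation). Cd8a reached 2200 ± 302 from 367 ± 124, while Cd4 stood at 962 ± 144 and 711 ± 116 (adjusted p = 0.0933). Cytotoxic effector genes had 11 of 17 members higher and 2 lower, and 11 higher and 3 lower adjusted over the list alone (set test adjusted p = 0.000101, and adjusted p = 0.135 with an estimated correlation). The chemokine gene Ccl5 rose from 450 ± 117 to 5830 ± 1400 (log2 change 3.70 ± 0.24, adjusted p = 4.81e-07) and Gzmb from 90 ± 13.7 to 981 ± 41.8. The members that fell were Gzma, a granzyme that natural killer cells also carry, and Cx3cr1, a receptor that monocytes also carry. The adjusted p of Gzma was 0.0115, and 0.0551 without untreated replicate 3, and that of Cx3cr1 was 0.0144, and 0.0546 with no intensity trend. Checkpoint genes had 9 of 14 members higher, and 10 adjusted over the list alone (set test adjusted p = 6.3e-05, and adjusted p = 0.0897 with an estimated correlation). The inhibitory receptor genes Lag3 and Havcr2 went from 352 ± 44.1 to 1260 ± 89.2 and from 68.7 ± 11.9 to 509 ± 99.3, and Tox from 40.3 ± 9.29 to 610 ± 46.5. Regulatory T cell genes had 3 of 6 members higher, and 3 adjusted over the list alone, one of them Ctla4 at 38 ± 7.55 before and 198 ± 47.5 at day 18 (set test adjusted p = 0.00129, and adjusted p = 0.135 with an estimated correlation). Ctla4 also stands in the checkpoint list and Foxp3 is not analysed here, so this rise need not mark regulatory T cells. The CD137 and NF-kB list had 5 of 13 members higher, and 6 adjusted over the list alone (set test adjusted p = 0.00546, and adjusted p = 0.216 with an estimated correlation).

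Interferon gamma response genes had 21 of 27 members higher and none lower, and 24 higher and 1 lower adjusted over the list alone (set test adjusted p = 0.000101, and adjusted p = 0.12 with an estimated correlation). Cxcl9 rose from 86 ± 24.3 to 716 ± 122, Gbp2 from 529 ± 90.8 to 4140 ± 876, and the transcription factor gene Irf1 from 2330 ± 173 to 5710 ± 281. All 12 MHC class I genes rose, over all genes and adjusted over the list alone (set test adjusted p = 2.55e-06, and adjusted p = 0.0603 with an estimated correlation). H2-Q6 went from 3150 ± 279 to 13200 ± 642 (log2 change 2.08 ± 0.09, adjusted p = 7.49e-09) and B2m, the light chain of class I molecules, from 26800 ± 1180 to 61000 ± 4180. Inflammatory cytokines and chemokines had 6 of 16 members higher, and 7 higher and 1 lower adjusted over the list alone (set test adjusted p = 0.00605, and adjusted p = 0.25 with an estimated correlation). The monocyte chemokine gene Ccl8 went from 1.67 ± 1.53 to 66 ± 14.1. With a mean normalised count of at least 40 this list had an adjusted p = 0.051. Secretory and unfolded protein response genes had 7 of 14 members higher, and 7 adjusted over the list alone, with the chaperone gene Hspa5 at 11500 ± 953 before and 18800 ± 1390 at day 18 (set test adjusted p = 6.3e-05, and adjusted p = 0.0737 with an estimated correlation). Immediate early and heat shock genes had 6 of 9 members higher, and 8 adjusted over the list alone, with Jun at 2950 ± 991 against 1290 ± 491 (set test adjusted p = 0.00207, and adjusted p = 0.135 with an estimated correlation).

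Natural killer cell genes had 10 of 12 members lower and 1 higher, over all genes and adjusted over the list alone (set test adjusted p = 0.0237, and adjusted p = 0.313 with an estimated correlation). The set test gave an adjusted p = 0.0601 and 0.0796 without untreated replicate 2 or 3. The receptor gene Klrb1c fell from 192 ± 30.6 to 58.7 ± 28.4 (adjusted p = 0.0041) and Klra7 from 176 ± 21.5 to 49.7 ± 14.5 (adjusted p = 0.000154). The member that rose was Il2rb, a cytokine receptor chain that activated T cells share, from 1300 ± 262 to 3660 ± 371 (adjusted p = 0.000194). At day 4 none of the 12 passed over all genes, 2 were higher adjusted over the list alone, and the set test gave an adjusted p = 0.454 with fry and 0.0756 with camera at a preset correlation. At day 11 4 were lower and 1 higher, and 8 lower and 1 higher adjusted over the list alone, with an adjusted p = 0.0643 by fry, while camera at a preset correlation gave an adjusted p = 7.2e-05, and adjusted p = 0.337 with an estimated correlation.

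Mature B cell genes had 11 of 12 members lower, and all 12 adjusted over the list alone (set test adjusted p = 0.00129, and adjusted p = 0.139 with an estimated correlation), with Fcer2a at 125 ± 30.6 against 879 ± 253 and Bank1 at 326 ± 40.1 against 897 ± 144. Immunoglobulin constant region genes had 5 of 12 members lower, and 8 adjusted over the list alone (set test adjusted p = 0.0127, and adjusted p = 0.204 with an estimated correlation). Ighd, the constant region of naive B cells, fell from 2800 ± 904 to 821 ± 227. Neutrophil primary granule genes had 8 of 12 members higher, and 11 adjusted over the list alone (set test adjusted p = 0.00435, and adjusted p = 0.223 with an estimated correlation), while the mature neutrophil list had none of 16 members changed and an adjusted p = 0.823. Cst7, which encodes an inhibitor of cathepsins and is in the primary granule list, rose from 663 ± 50.6 to 1090 ± 48.5. The primary granule list shares Nkg7 with the cytotoxic effector list, so its rise need not mark neutrophils alone. Basophil and mast cell genes had 6 of 9 members higher, and 7 adjusted over the list alone, with the mast cell protease gene Cpa3 at 942 ± 74.8 before and 1720 ± 214 at day 18 (set test adjusted p = 0.00199, and adjusted p = 0.135 with an estimated correlation).

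Eosinophil genes split at day 18: 6 of 10 rose and 2 fell, over all genes and adjusted over the list alone (set test adjusted p = 0.0444, and adjusted p = 0.34 with an estimated correlation). The granule protein genes Epx and Ear6 rose from 649 ± 216 to 1630 ± 322 and from 86 ± 24 to 288 ± 62.7, whereas the receptor genes Ccr3 and Il5ra fell from 220 ± 40.4 to 94.3 ± 7.64 and from 103 ± 21.7 to 49.3 ± 9.02. Conventional dendritic cell genes had 2 of 10 members lower, and 3 adjusted over the list alone (set test adjusted p = 0.0398, and adjusted p = 0.313 with an estimated correlation), among them the migration receptor gene Ccr7, from 377 ± 78.8 to 202 ± 42. Osteoclast genes had 1 of 6 members lower, the acid phosphatase gene Acp5, from 806 ± 161 to 506 ± 54.5 (set test adjusted p = 0.0398, and adjusted p = 0.263 with an estimated correlation). Of 3 skeletal muscle genes 1 was lower (set test adjusted p = 0.0398, and adjusted p = 0.326 with an estimated correlation). These calls were close to the threshold. The eosinophil value was 0.0529 to 0.152 without untreated replicate 1 or 2, day 4 replicate 1, 2 or 3, day 11 replicate 2, or day 18 replicate 1, 2 or 3. The dendritic value was 0.0537 to 0.119 without untreated replicate 2 or 3, day 4 replicate 1, day 11 replicate 1, 2 or 3, or day 18 replicate 1 or 2. The osteoclast value was 0.0565 to 0.111 without untreated replicate 3, day 4 replicate 1, 2 or 3, day 11 replicate 1, or day 18 replicate 1 or 3. The muscle value was 0.0512 to 0.171 without any 1 sample other than day 11 replicate 3 and day 18 replicate 1, and 0.653 with no filter on low values. At a preset correlation the osteoclast and muscle lists had an adjusted p = 0.0603 and 0.161.

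Resident macrophage genes had 7 of 16 members lower at day 18 and none higher, and 1 higher and 8 lower adjusted over the list alone, with a set test adjusted p = 0.0527 and 0.000464 in its mixed form, while camera at a preset correlation gave an adjusted p = 0.000392, and adjusted p = 0.36 with an estimated correlation. The haemoglobin scavenger receptor gene Cd163 fell from 666 ± 129 to 260 ± 51.6 (log2 change -1.36 ± 0.18, adjusted p = 0.000378) and the lipid carrier gene Apoe from 4520 ± 801 to 2010 ± 189 (log2 change -1.16 ± 0.19, adjusted p = 0.00149). Erythroid genes had 6 of 19 members lower, and 11 adjusted over the list alone (set test adjusted p = 0.061 by fry), while camera at a preset correlation gave an adjusted p = 3.33e-06, and adjusted p = 0.343 with an estimated correlation. The plasma cell and myeloma list had 2 of 14 members higher and 3 lower, and 3 higher and 5 lower adjusted over the list alone (set test adjusted p = 0.51, mixed form 4.36e-06). Among single genes, the collagen gene Col14a1 fell from 126 ± 35.8 to 10.7 ± 6.11 (adjusted p = 0.000626) and the lectin gene Cd209f from 64.7 ± 12.5 to 3.33 ± 2.89 (adjusted p = 0.000809), and Coch, an extracellular matrix gene, rose from 1 ± 1 to 52.7 ± 12.7 (adjusted p = 0.00105).

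The remaining lists did not pass with fry at day 18. The adjusted p was 0.386 for type I interferon response, 0.225 for B cell precursor, 0.673 for monocyte, 0.531 for plasmacytoid dendritic cell, 0.169 for haematopoietic stem and progenitor and 0.957 for megakaryocyte and platelet genes. It was 0.823 for osteoblast, 0.831 for mesenchymal stroma, 0.44 for endothelial, 0.0633 for adipocyte and 0.0549 for cell cycle genes. Camera at a preset correlation called 3 of these lists, with an adjusted p = 0.0113 for type I interferon, 0.0102 for B cell precursor and 0.000576 for cell cycle genes, and these had adjusted p = 0.657, 0.543 and 0.389 with an estimated correlation. Over the 3 days, 44 of the 102 list tests passed with fry and 56 with camera at a preset correlation, and none did with an estimated correlation.

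**Figure D2:**
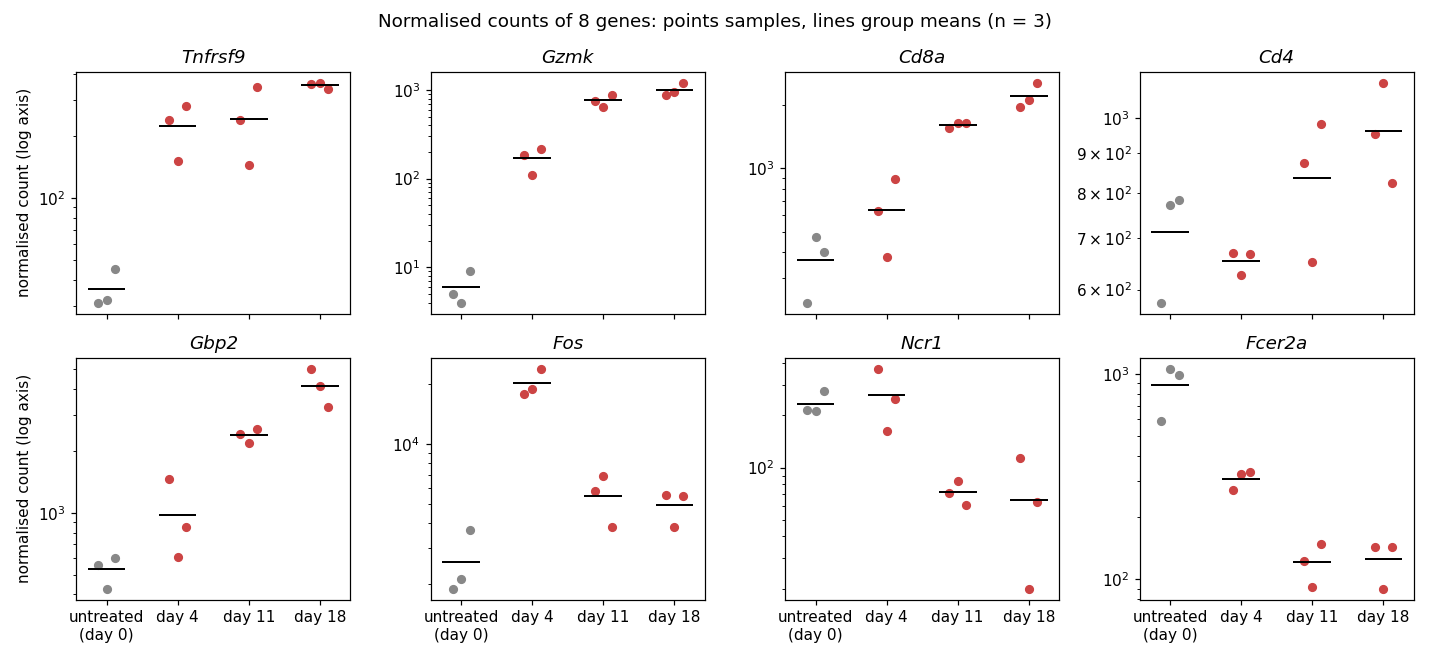
Normalised counts on a log axis of 8 genes in the 12 samples by treatment day, with points for samples and lines for group means. Gzmk, Cd8a, Gbp2 and Tnfrsf9 have higher means at day 18 than before treatment, Ncr1 and Fcer2a lower ones, and Fos has its highest mean, 20100, at day 4.

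Comparing treated days with each other shows which changes went on. Between day 4 and day 11 the immediate early list moved down, with 5 of 9 members lower and none higher (median log2 change -1.84, set test adjusted p = 0.00167, and adjusted p = 0.116 with an estimated correlation), while the MHC class I list moved up, with 8 of 12 members higher and none lower (median log2 change 0.45, adjusted p = 0.00093, and adjusted p = 0.107 with an estimated correlation). At day 18 interferon gamma response genes stood higher than at day 4, with 18 of 27 members higher and none lower (median log2 change 1.04, adjusted p = 0.00167, and adjusted p = 0.178 with an estimated correlation). Among genes, 108 were higher and 142 lower at day 11 than at day 4, and 413 higher and 402 lower at day 18 than at day 4. Between day 11 and day 18 a single gene passed, Lag3, from 688 ± 57.9 to 1260 ± 89.2 (log2 change 0.87 ± 0.11, adjusted p = 0.0168), and 1040 genes had an unadjusted p under 0.05. For Lag3 the adjusted p was 0.0904, 0.144 and 0.0557 without day 11 replicate 1, 2 or 3, 0.058 without day 18 replicate 2, and 0.0971 with no intensity trend.

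These counts moved with single samples. The 250 genes between day 4 and day 11 were 141 without day 4 replicate 3 and 136 and 147 without day 11 replicate 1 or 3. The 815 genes between day 4 and day 18 were 489 and 468 without day 4 replicate 2 or 3 and 433 without day 18 replicate 2. Their more frequent direction changed as well: 225 were higher and 264 lower without day 4 replicate 2, 249 and 340 without day 18 replicate 1, and 209 and 224 without day 18 replicate 2. It was 376 and 389 with no filter, 372 and 375 with a mean normalised count of at least 40, 269 and 274 with no intensity trend, 232 and 247 with only the 2 groups compared, and 353 and 373 after thinning to 1 depth. Between day 4 and day 11 it changed without day 4 replicate 3, to 71 higher and 70 lower. The 1 gene between day 11 and day 18 became 28 without untreated replicate 1, 8 and 2 without day 4 replicate 1 or 2, 3 and 15 without day 18 replicate 1 or 3, and 0 without day 11 replicate 1, 2 or 3 or day 18 replicate 2. The other settings that moved these counts by over 1.5 times stand with the processing choices in the closing part.

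Across the 4 time points 1410 genes differed by the F-test, and 872 without untreated replicate 3. By direction, 147 genes were higher than before treatment at days 4, 11 and 18, and 80 were lower at each. A further 270 were called higher and 119 lower at days 11 and 18 but not at day 4, and 147 higher and 182 lower at day 4 alone. The overlap of the calls was far above that of independent lists: days 11 and 18 shared 417 rises and 200 falls, where 25.2 and 12.4 would be expected. All 3 comparisons use the same untreated samples, which by itself gives correlated changes. Across genes, which are not independent replicates, the log2 changes of days 11 and 18 had r = 0.819, against 0.479 in 100 simulated data sets with shared controls and no real change. For days 4 and 11 r was 0.618 against 0.425, and for days 4 and 18 it was 0.56 against 0.462. Part of the excess can still come from the untreated samples, since a group of 3 cannot be divided into separate sets of controls of enough samples each.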

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

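The tests of handling, T cell numbers, dilution and shared reads below were chosen only after the results were seen, as was thinning to 1 depth, while the other splits of the samples were planned.

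Immediate early transcripts were high at day 4 (median log2 change 3.02) and lower at later days, by -1.84 at day 11 and -1.82 at day 18 against day 4. The fall from day 4 to day 18 had an adjusted p = 0.00297, and adjusted p = 0.241 with an estimated correlation, and the call held without any 1 sample. T cell core genes had a median log2 change of 1.05 there, with 13 of 16 members higher and none lower (adjusted p = 0.0217, and adjusted p = 0.302 with an estimated correlation). That call was lost without day 18 replicate 2 or 3, with adjusted p up to 0.0601. Immediate early transcripts that fell while T cell transcripts did not fall argue against T cells that became more numerous as the source. With every library thinned to 1 depth the median at day 4 was 3.01 (adjusted p = 2.78e-05). Thinned counts were scaled back up, so their expected values did not change, and genes with counts as high as these could hardly move. The result therefore cannot speak for or against the lower depth of those libraries. Handling of the marrow on the day of collection cannot be told apart from an effect of the antibody or of days since myeloma injection, because no collection dates are at hand and each group may have been collected on a day of its own. The same limit holds for Tnfaip3, Cxcl2, Rgs1, Ccl2 and Dnajb9, which were also highest at day 4 and lower in every day 11 sample. Tnfrsf9 and Ccl8 had means at day 11 that were not lower than at day 4.

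Natural killer cell transcripts were low at day 18, with a median log2 change of -1.78 against untreated marrow, -1.92 against day 4 (adjusted p = 0.0182, adjusted p = 0.302 with an estimated correlation, and 0.0568 without day 4 replicate 3), and -1.50 at day 11 against day 4. Dilution by RNA of other cells would lower all transcripts that did not rise, but the mature neutrophil list had a median of -0.02 (SD of its 16 members 0.23, range -0.54 to 0.28). Neutrophil transcripts are among the most abundant here, and the scaled values had a median change of 0 over all genes at day 18. A neutrophil list near 0 therefore cannot speak against dilution by neutrophil RNA itself. Reads shared between Klra paralogs would spare other genes, but the 8 members outside that family had a median of -1.36, with 6 lower and 1 higher. After thinning the list's median at day 18 was -1.71 (adjusted p = 0.0323). Since thinning leaves expected values as they were, this could hardly have come out otherwise and does not decide on depth. Fewer natural killer cells, or less of these transcripts per cell, may account for it as a hypothesis, and whether the antibody or the growth of myeloma is behind it was not tested.

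Other gene lists differed between treated days by a test of the difference itself, and medians of log2 changes follow. At day 11 against day 4, T cell core genes had 0.88 (adjusted p = 0.0488), interferon gamma response genes 0.50 (adjusted p = 0.0322), MHC class I genes 0.45, immunoglobulin constant region genes -1.07 (adjusted p = 0.0207) and mature B cell genes -0.82 (adjusted p = 0.0206). In that order they had adjusted p = 0.302, 0.274, 0.107, 0.241 and 0.241 with an estimated correlation. Secretory and unfolded protein response genes had a median of 0.01 there, while the test pointed down (adjusted p = 0.0486, and adjusted p = 0.326 with an estimated correlation). At day 18 against day 11, interferon gamma response genes had 0.50 (adjusted p = 0.0488), MHC class I genes 0.36 (adjusted p = 0.00403) and secretory genes 0.18 (adjusted p = 0.00966). These had adjusted p = 0.241, 0.107 and 0.135 with an estimated correlation. At day 18 against day 4, cytotoxic effector genes had 0.94 (adjusted p = 0.0486), checkpoint genes 0.54 (adjusted p = 0.00403), interferon gamma response genes 1.04, MHC class I genes 0.78 (adjusted p = 3.44e-05), erythroid genes -0.88 (adjusted p = 0.0234) and basophil and mast cell genes 0.32 (adjusted p = 0.0488). In turn these had adjusted p = 0.519, 0.241, 0.178, 0.107, 0.302 and 0.326 with an estimated correlation.

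Of the 20 differences between lists at treated days, 8 kept their call without any 1 sample: those of MHC class I genes in each comparison, immediate early genes, checkpoint genes and interferon gamma response genes at day 18 against day 4, immediate early genes at day 11 against day 4, and secretory genes at day 18 against day 11. T cell core genes at day 18 against day 4 had adjusted p up to 0.0601, lost without day 18 replicate 2 or 3, and erythroid genes up to 0.086, lost without day 4 replicate 2 or 3 or day 18 replicate 2. Immunoglobulin constant region and mature B cell genes at day 11 against day 4 reached 0.0568 and 0.061 and were lost without day 4 replicate 2 or 3 or day 11 replicate 1 or 2. At day 11 against day 4, T cell core genes (up to 0.129) kept their call only without untreated replicate 1, natural killer genes (adjusted p = 0.0375, adjusted p = 0.302 with an estimated correlation, up to 0.101 without 1 sample) without day 4 replicate 2 or any 1 day 18 sample, interferon gamma response genes (up to 0.0938) without day 4 replicate 1 or day 18 replicate 1 or 3, and secretory genes (up to 0.111) without untreated replicate 3 or day 18 replicate 1 or 3. Interferon gamma response genes at day 18 against day 11 (up to 0.137) kept theirs without day 4 replicate 1 or 2 or day 18 replicate 3. At day 18 against day 4, cytotoxic effector genes (up to 0.12) kept theirs without day 4 replicate 1 or 2, and basophil genes (up to 0.158) without day 11 replicate 1 or 2. These 7 calls were lost without each of the other samples. With camera at an estimated correlation 0 of the 102 tests between treated days passed, with a lowest adjusted p of 0.107.

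Of the named genes, 23 differed between day 18 and day 4 by a log2 change of at least 2 in either direction with an adjusted p under the threshold. Higher at day 18 were Coch (4.61), Faxc (4.19), Gcg (3.70), Apol11a (3.26), Ccl5 (2.90), Ccl8 (2.78), Tmprss13 (2.77), Pdcd1 (2.60), Gzmk (2.59), Tgtp1 (2.41) and Tox (2.25). Lower at day 18 were Fos (-2.02), Lad1 (-2.41), Rgs1 (-2.45), Jun (-2.47), Klra7 (-2.57), Cxcl2 (-2.84), Atf3 (-2.96), Col14a1 (-3.28), Cd209f (-3.88), Klra4 (-4.06), Klra8 (-4.27) and Fosb (-4.33). The adjusted p of Lad1 was 0.0166, and 0.052, 0.0775 and 0.0725 without day 4 replicate 1 or 3 or day 18 replicate 2, and 0.0514 with no intensity trend. That of Klra8 was 0.0172, and 0.054 and 0.0713 without day 4 replicate 1 or 3. It was 0.0561 with a pseudocount of 0.1, 0.0693 with no intensity trend, 0.0748 with a robust trend and 0.0699 with only the 2 groups compared. Ccl8 had an adjusted p = 0.0908 with a pseudocount of 0.1. With the depth covariate, Lad1 had a log2 change of -2.36 ± 0.70 (adjusted p = 0.117, against -2.41 ± 0.53 without it), Klra8 -4.47 ± 1.24 (adjusted p = 0.0932, against -4.27 ± 0.95) and Gcg 2.96 ± 0.72 (adjusted p = 0.0547, against 3.70 ± 0.61). The SE was wider in each, and the change was smaller in Gcg. The other 19 genes kept their call under every alternative run for single genes.

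The 3 samples of a day and the 3 of another make only 10 splits, too few for a share under 0.05. In each of the 6 comparisons 1 split, the real one, called as many genes, with 691 at day 4, 792 at day 11 and 1369 at day 18 against untreated marrow, 250 and 815 at days 11 and 18 against day 4, and 1 at day 18 against day 11. The highest other split called 0 genes in each. For the F-test, 1 of 100 regroupings of the 12 samples, the real one, called 1410 genes, and the highest other called 355. Chance is therefore an unlikely source of that count. The regroupings cannot speak to a collection day that all samples of a group may share.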

How the results depend on the processing

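The alternatives on depth (thinning, voom weights and a depth covariate) were chosen only after the results were seen, and all others were planned. Under pseudocounts of 0.1, 0.5 and 4, the stricter filter, the rescalings and a robust trend, every count of genes stayed within 1.5 times its value. With no filter, 3 genes differed between day 11 and day 18, against 1. With no intensity trend the counts were 416 at day 4, 521 at day 11, 141 between days 4 and 11, 0 between days 11 and 18, 543 between days 4 and 18 and 937 by the F-test. Sample weights gave 1817, 1914 and 2056 at days 4, 11 and 18, then 763, 151 and 1844 between days 4 and 11, 11 and 18, and 4 and 18, and 3154 by the F-test. With only the 2 groups compared, 14 genes differed between days 11 and 18 and 479 between days 4 and 18. A log2 change of at least 1 left 189, 340 and 499 genes at days 4, 11 and 18, and 128, 0 and 292 between days 4 and 11, 11 and 18, and 4 and 18, by its construction. Thinning gave 3 genes and voom weights 7 between days 11 and 18. With the depth covariate the counts were 69 at day 4, 442 at day 11, 339 between days 4 and 18 and 925 by the F-test, and thinning to 1 depth gave 600 at day 4 and 730 at day 11. The covariate follows the groups, since every day 4 library is shallower than every untreated one. Apart from that and from the minimum change, the cause was not tested. Without 1 sample, the counts were 269 to 1089 at day 4, 407 to 1134 at day 11, 804 to 1413 at day 18, 136 to 341 between days 4 and 11, 0 to 28 between days 11 and 18, 433 to 1120 between days 4 and 18 and 872 to 1890 by the F-test. Of the list tests, 35 to 44 passed without 1 sample, 56 with camera at a preset correlation and 0 at an estimated one, where the lowest adjusted p was 0.0603 and 27 had an unadjusted p under 0.05. For the 511 results of single genes, 12527 of 13756 alternative values kept direction and call, 1229 kept the direction and lost the call, and 0 reversed. For the 44 lists called, the numbers were 885 of 1012, 127 and 0. The count-model alternative was not run, because the values are rounded normalised counts. At this depth and group size, 51% of genes with a 1.5-fold change at day 4 were called on simulated data, in which the lowest genes were not changed. A gene that did not pass may therefore still differ.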

Other observations

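The 3 genes below were chosen after their values were seen, and so were the test of a shared clone and the repeats with samples left out, while the tests against immunoglobulin transcripts in general and against depth were written before their results.

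Among 173 variable segments of immunoglobulin genes tested, 2 had the highest means over the 12 samples: the light chain segment Igkv4-91 (chromosome 6, 68768555 to 68769103, minus strand) with a mean of 2070 normalised counts, and the heavy chain segment Ighv1-15 (chromosome 12, 114657353 to 114657786, minus strand) with 1940. The next segment had a mean of 403. By group, the highest other segment had a mean of 491 before treatment and 477, 341 and 350 at days 4, 11 and 18. Both segments exceeded every other one in 9 of the 12 samples, but not in day 4 replicate 2 or day 11 replicate 1 or 3. Igkv4-91 stood at 4020 ± 2320 before treatment (SD, n = 3), and at 2840 ± 2440, 582 ± 30.6 and 840 ± 337 at days 4, 11 and 18. These differences did not pass with limma (adjusted p = 0.428, 0.117 and 0.162), and neither did those of Ighg2b, a heavy chain constant region (chromosome 12, 113302965 to 113307933, minus strand), at 9030 ± 5290 before treatment and 6920 ± 5440, 1710 ± 159 and 2180 ± 797 after (adjusted p = 0.518, 0.101 and 0.122). Day 4 replicate 2 was low, with 155 for Igkv4-91, 196 for Ighv1-15 and 754 for Ighg2b. The other 171 segments had a median log2 change of -0.90 at day 11 and at day 18, with 19 and 18 of them called lower.

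Igkv4-91, Ighv1-15 and Ighg2b varied together over the 12 samples. Igkv4-91 had r = 0.995 and rho = 0.993 with Ighv1-15, and r = 0.992 and rho = 0.993 with Ighg2b, by permutation tests with p = 1e-05, the smallest that 100000 permutations can give, and 0.000915 after adjustment over 183 relations. Without untreated replicate 1 and day 4 replicate 2, the samples farthest from the median of Igkv4-91, r was 0.997 and 0.994, but other immunoglobulin genes then had high values too, among them Ighv14-3 with 0.94, Igha with 0.919, Igkv6-17 with 0.913 and Igkc with 0.906. These values include the differences between groups. Of 14882 genes, Ighv1-15 and Ighg2b were the closest to it. After group means were taken out, r with Ighv1-15 was 0.996 (permutation p = 0.00163 within groups) and with Ighg2b 0.994 (permutation p = 0.00234 within groups), while the next variable segment, Ighv1-53, had 0.794. In these values r with the mean of the other segments was 0.0231 (permutation p = 0.901), and with the estimated number of reads -0.0671 (permutation p = 0.746), which argues against depth. Much of the spread within groups came from day 4 replicate 2. Without it r was 0.985 with Ighv1-15, 0.976 with Ighg2b and 0.106 with the mean of the other segments (permutation p = 0.795), or 0.764 with the differences between groups kept. Without any 1 sample the value with group means taken out lay between -0.125 and 0.142, while a single other segment reached 0.898, Ighv1-53 without untreated replicate 1. Without both farthest samples it was 0.453 (permutation p = 0.465), against 0.972 with Ighv1-15 and 0.944 with Ighg2b, and Ighv2-2 reached 0.905. Within groups, the general level of immunoglobulin transcripts is therefore argued against as the whole source by all 12 samples and by each set of 11, and less clearly by the 10 without both. Between groups, these genes had lower means at days 11 and 18, where the median of the other segments was lower too, so the argument does not extend to those differences. A candidate explanation is that 1 plasma cell or myeloma clone that joins these segments to Ighg2b makes up a varying part of the marrow, which would follow myeloma load in each sample. It remains a hypothesis, since no myeloma burden was analysed here and the antibody sequence of Vk12653 was not compared.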
